A study of Paracoccus denitrificans PD1222 with 5 samples.

How the data were processed

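Total RNA from cultures of Paracoccus denitrificans PD1222 was depleted of ribosomal RNA with a commercial kit, made into stranded cDNA libraries and sequenced on an Illumina NextSeq 500, per the labels' protocols. The submitters' processing notes name bcl2fastq, bedtools and DESeq2 without versions or order. The aligner, the genome build and the strand setting of the counting are not given in the sources used here, so reads from overlapping or antisense genes could not be told apart.

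The deposited table holds whole-number read counts per gene for 5 libraries, made by the authors, with 4948 rows. It also holds the authors' normalized signal per library, which equals the count divided by the DESeq2 size factor recomputed here for that library, with a largest relative difference of 4.93e-10. A log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value per gene complete the authors' deposited comparison. DESeq2 1.42.0 run here on the counts with default settings gave the same log2 fold changes to within 1.02e-08. The 192 rows whose adjusted p DESeq2 leaves undefined are listed at 1 in the authors' deposited table. The labels' protocols state a threshold of adjusted p under 0.05, whereas the 145 calls in the deposited table were exactly the rows with adjusted p under 0.01 and an absolute log2 fold change over 1.

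The table identifies 4899 protein-coding genes by locus tag alone and does not pair them with gene names or products, and no annotation was used here. Of 33 gene lists written before the data were examined, only 1, the structural RNAs, could be matched, through the gene type and notes in the table. Locus-tag numbers written from recall for some of the other lists were not used, because no table supported them, and named metabolic or respiratory genes were therefore not analysed here. At most 2 locus tags are printed in each direction. The rule fixed beforehand named a set of denitrification and respiration genes by symbol, which could not be matched. It also named up to 10 genes per direction past the edgeR test, with a mean of at least 20 counts, a known product and every treatment library beyond every control. From each list it took the 4 members of smallest p. No gene passed the edgeR test, so the 4 protein-coding genes named are those of smallest edgeR p in each direction, a choice made after their values were seen. The ribosomal RNA rows, the ribonuclease P RNA and ffs were likewise added afterwards.

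Libraries were grouped by their titles into control (0 mV, 2 libraries) and treatment (+200 mV, 3 libraries). Differences were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group (which removed 0 rows), a quasi-likelihood F-test with robust estimation over all 5 libraries, and Benjamini-Hochberg adjustment at 0.05. Normalised levels are CPM (counts scaled to a common library size) on the TMM scale, given as mean ± SD. The standard error of a fold change is its size divided by the square root of the F statistic. The list was tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and with an estimated one. With a single list tested, its adjusted p equals its p. Single values were compared by exact permutation over the 10 possible splits of 5 libraries into 2 and 3, which cannot give a two-sided p below 0.1. Nothing in the labels ties equal replicate numbers to a shared day or culture, and no label states that each library came from its own culture, although the design text speaks of replicate cultures. P-values therefore measure the spread between these libraries, part of which can be technical.

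Tests were tried on simulated data drawn from the real genes' means, library sizes and spread, with 200 of 4948 genes changed. For this comparison, edgeR called 18.2% of genes changed by a log2 fold change of 1 in either direction. It called 97.0% of those changed by 2 and 100% of those changed by 3 upwards, with 97.1% and 94.1% downwards. These data had the same spread in both groups, estimated for each gene. A second simulation used the spread measured in each group, smoothed over genes of similar level. There edgeR called 3.03% upwards and 6.06% downwards at 1, 87.9% and 91.2% at 2, and 100% at 3. Both simulations drew genes independently, whereas real neighbours moved together, so these shares need not hold for the real data. Both also used spreads smoothed towards those of other genes. In the real fit not even Pden_2067, at a log2 fold change of -3.65, was called (edgeR adjusted p = 0.137). Finding 0 calls therefore does not show that large changes were absent. For the same comparison, 20 further simulations of 4948 genes with no changed gene gave each group its own measured spread, with the controls drawn either as 2 cultures or as 1 culture. Alternatives were other scalings, no filter on low counts, DESeq2, limma-voom, no robust estimation, a replicate block, a fold threshold, protein-coding genes only and each library left out. Those fixed before the data were examined are distinguished in the closing section from those added later.

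Depth was 19398625 to 22880270 counts per library, and at most 8 of 4948 rows had under 10 counts in any library. The SD of log2 ratios between the controls, 0.184, bounds the counting error of a typical gene from above.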

Results

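RNA-seq gave 5 libraries of the denitrifying soil bacterium Paracoccus denitrificans PD1222. This organism can respire nitrate stepwise to dinitrogen gas when oxygen is absent. Cells pre-grown in rich medium were moved to anaerobic minimal medium in a reactor of 1.5 L, with succinate at 3.5 mM and nitrate at 7.5 mM. An electric potential of 0 mV (control, n = 2) or +200 mV (treatment, n = 3) was then applied for 6 h. The comparison asks which transcripts differ between the potentials. The design text names 3 cultures per potential, and 2 control libraries were analysed here. The control libraries held 20921465 and 22351588 counts. The treatment libraries held 22880270, 19398625 and 19583241 counts.

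At +200 mV the protein-coding transcripts with the smallest p were Pden_2225 and Pden_1760, which were higher, and Pden_2067 and Pden_5069, which were lower. The table gives these genes a locus tag and no name, so their functions are not stated. Pden_2225 averaged 116 ± 0.213 CPM (SD, n = 2) at 0 mV and 445 ± 53.9 (SD, n = 3) at +200 mV, a 3.84-fold difference. Pden_1760, an abundant transcript, averaged 557 ± 4.81 (SD, n = 2) and 1737 ± 96.1 (SD, n = 3), a 3.12-fold difference. Pden_2067 averaged 14.9 ± 0.237 (SD, n = 2) at 0 mV and 1.18 ± 0.605 (SD, n = 3) at +200 mV, which is 12.5-fold lower. Its raw counts were 334 and 403 in the controls and 35, 21 and 11 in the treatment libraries. Pden_5069 averaged 77.2 ± 5.57 (SD, n = 2) and 26.8 ± 2.88 (SD, n = 3), which is 2.88-fold lower. The SDs at 0 mV rest on 2 libraries of genes chosen by small p, so very small ones can be chance agreement. For all 4 genes, every treatment library lay on the same side of both controls, as in 48.3% of all rows. Choosing genes by small p favours such separation, so it is not added support.

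**Figure D1:**
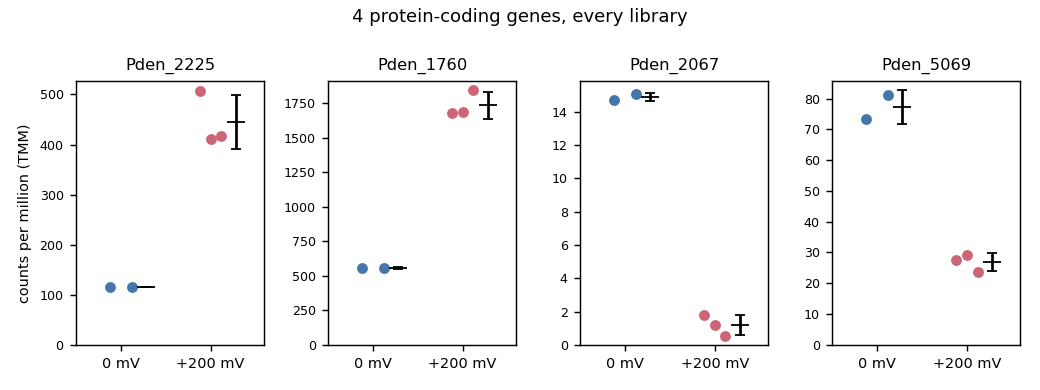
Normalised level of 4 protein-coding genes in every library. The vertical axis of each panel is CPM on the TMM scale, points are libraries, and the bar beside them is mean ± SD (n = 2 at 0 mV, n = 3 at +200 mV). Pden_2225 and Pden_1760 were higher and Pden_2067 and Pden_5069 lower in all 3 treatment libraries.

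None of these differences passed the test chosen beforehand. The log2 fold changes were 1.94 ± 0.23 (SE) for Pden_2225, 1.64 ± 0.20 for Pden_1760, -3.65 ± 0.40 for Pden_2067 and -1.53 ± 0.20 for Pden_5069. Each had an adjusted p of 0.137 in edgeR's quasi-likelihood test, and each reached the smallest exact permutation p that 2 against 3 libraries allow, 0.1. In the authors' deposited table, made with DESeq2, the same genes had adjusted p values of 3.8e-13, 4.8e-13, 4.8e-13 and 2.9e-07. Over all alternatives run, the highest adjusted p was 0.295 for Pden_2067 and 0.825 for Pden_2225, Pden_1760 and Pden_5069, and no direction changed.

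Across all 4948 rows, edgeR called 0 genes higher and 0 lower at adjusted p under 0.05. At an unadjusted p under 0.05 there were 595 higher and 439 lower genes, 20.9% of those tested. These counts were 165 and 85 without control replicate 1, 151 and 89 without control replicate 2, and 884 and 709 without treatment replicate 3. By fitted size alone, 332 genes were over 2-fold higher and 98 over 2-fold lower. Some of those higher were raised mainly in treatment replicate 1, with another treatment library inside or below the range of the controls. DESeq2 on the same counts called 327 genes higher and 92 lower at adjusted p under 0.05. limma-voom called 0, with 557 higher and 468 lower genes at an unadjusted p under 0.05, and with library weights it called 684 higher and 522 lower. The authors' deposited table marks 126 genes as higher and 19 as lower at its stricter rule, adjusted p under 0.01 with an absolute log2 fold change over 1. All 145 genes so marked in the authors' deposited table had an unadjusted edgeR p under 0.05. Both tests used the same counts, so this is not separate evidence. When both control libraries were summed into a single library, DESeq2 called 2 genes higher and 1 lower, and with either control left out it called between 7 and 11 genes in all. Without treatment replicate 3 it called 679 higher and 345 lower, without treatment replicate 2 it called 187 and 70, and without treatment replicate 1 it called 362 and 165.

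Every treatment library lay above both controls for 1181 genes (23.9%) and below both for 1207 genes (24.4%). Chance gives 10% in each direction for 5 independent libraries of equal spread, and 25% if both controls were a single culture with equal values. The controls were not equal and spread less than the treatment libraries, so neither share is exact here. With DESeq2 size factors the shares were 25.2% above and 22.7% below. Scaling by library totals alone moved the median log2 fold change of all genes from 0.00 to -0.31. With that scaling 18.8% of the genes at unadjusted edgeR p under 0.05 were higher, against 57.5% with TMM, so the balance of higher and lower genes depended on the scaling.

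The control libraries were far closer to each other than any other pair. Over protein-coding genes the SD of the log2 count ratio was 0.184 between the controls, and 1.42% of genes differed by more than 1.5-fold. Between treatment libraries the SD was 0.654 for replicates 1 and 2, 0.785 for replicates 1 and 3, and 0.529 for replicates 2 and 3. Treatment replicate 3 was about as near to the controls (0.543 and 0.527) as to treatment replicate 2. Treatment replicate 1 was the farthest from the controls (0.907 and 0.906). The first principal component held 64.5% of the variance and placed the controls at -21.9 and -22.0, treatment replicate 3 at -4.65, replicate 2 at 7.58 and replicate 1 at 40.9. The second held 18.8% and set treatment replicate 3 farthest from the controls, at -22.4 against 10.2 and 8.89. The controls still differed by more than counting noise, with a median chi-square per gene of 1.54 against 0.455 for sampling alone, and they were kept as 2 libraries.

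**Figure D2:**
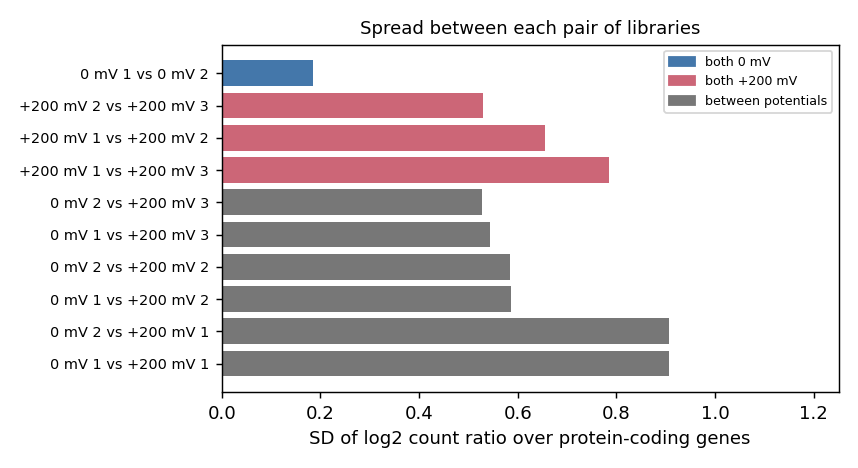
Spread between each pair of libraries. The horizontal axis is the SD of the log2 count ratio over protein-coding genes, and colours mark pairs within 0 mV, within +200 mV and between potentials. The pair of controls lies at 0.184 and all other pairs between 0.527 and 0.907.

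Among structural RNAs, the RNA of ribonuclease P, the enzyme that trims the 5′ ends of tRNA precursors, was among the most counted transcripts. It took 1.97% ± 0.293 of counts (SD, n = 2) at 0 mV and 3.79% ± 2.58 (SD, n = 3) at +200 mV, with treatment libraries ranging from 1.62% to 6.64%. Its log2 fold change was 1.23 ± 0.52 (SE), with an adjusted p of 0.242 in edgeR, and it was 0.67 without treatment replicate 3. The 6 ribosomal RNA rows left after depletion took 15.5% ± 4.65 (SD, n = 2) of counts at 0 mV and 22.0% ± 4.70 (SD, n = 3) at +200 mV (exact permutation p = 0.3, two-sided). The 4 abundant ribosomal rows had log2 fold changes of 0.72, 0.72, 1.41 and 1.41, with adjusted p from 0.228 to 0.273 in edgeR. They formed 2 pairs of near-equal counts, differing by at most 4.1% and 3.2% in any library, and are not 4 separate measurements. Without control replicate 1 they were 1.06, 1.08, 2.72 and 2.74, and without control replicate 2 they were 0.44, 0.43, 0.73 and 0.73. With library totals alone the first pair came to 0.41 and 0.42. The other 2 lay at -0.09 and -0.06. The controls themselves held 18.7% and 12.2% ribosomal RNA.

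Transfer RNAs took 0.0905% ± 0.00822 of counts (SD, n = 2) at 0 mV and 0.0927% ± 0.0589 (SD, n = 3) at +200 mV. Of 41 tRNA genes, 28 had a log2 fold change below 0 and 13 above, with a median of -0.26, and none passed edgeR, with 6 at an unadjusted p under 0.05. The smallest p belonged to tRNA-Pro2, at 8.51 ± 0.521 CPM (SD, n = 2) and 3.69 ± 1.02 (SD, n = 3). Its log2 fold change of -1.21 ± 0.27 (SE) had an adjusted p of 0.157 in edgeR and 0.010 in DESeq2, which called no other structural RNA. Over all alternatives its adjusted p ranged up to 0.825. tRNA-Gly3 followed at -1.14 ± 0.35, tRNA-Ala2 at -0.61 ± 0.19 and tRNA-Pro3 at -0.59 ± 0.22, with edgeR adjusted p of 0.177, 0.179 and 0.215. With library totals alone tRNA-Ala2 and tRNA-Pro3 came to -0.93 and -0.90, beside the shift of -0.31 in all genes. The signal recognition particle RNA gene ffs, which encodes the RNA of the particle that targets nascent membrane proteins, had 15 to 58 counts per library and a log2 fold change of -0.08 ± 0.55.

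The 49 structural RNAs were the list that could be tested as a group. In edgeR 0 passed over all genes and 0 adjusted over the list alone, with 8 at an unadjusted p under 0.05, and DESeq2 called 1. Their median log2 fold change was -0.14 and their mean 0.00, and camera gave p = 0.0795 with its preset correlation and p = 0.356 with an estimated correlation. With limma's camera at its preset correlation the list was called when treatment replicate 1 (adjusted p = 0.00972) or treatment replicate 2 (adjusted p = 0.0318) was left out. An estimated correlation was not tried with a library left out. Split after the data were seen, the 41 tRNAs gave a camera p of 0.00535 towards lower and the 6 ribosomal rows 0.0349 towards higher. Of these 6 rows, 4 formed 2 pairs of near-equal counts. Neither the tRNA nor the ribosomal result held with an estimated correlation in camera (p = 0.207 and p = 0.298).

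**Figure D3:**
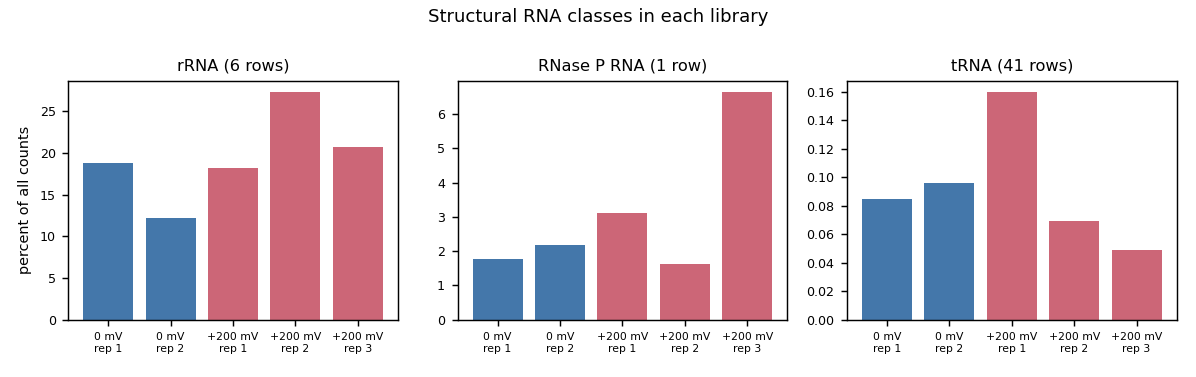
Share of all counts taken by ribosomal RNA, ribonuclease P RNA and transfer RNA in each library. The vertical axes are percent of counts, and bars are single libraries. Ribonuclease P RNA reached 6.64% in treatment replicate 3 and tRNA 0.160% in treatment replicate 1.

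Genes with consecutive locus-tag numbers, which usually lie side by side, moved together. Over 4753 such pairs of protein-coding genes, the log2 fold changes of the 2 neighbours correlated across genes with r = 0.512, where shuffled gene order reached at most 0.0619 in 10000 draws (permutation p = 1e-04, the smallest they can give). Neighbouring genes are not independent replicates. The same correlation was 0.440 to 0.473 for the ratios between treatment libraries and 0.0846 for the ratio of the controls. DESeq2 calls formed 24 runs of 3 or more consecutive genes, 21 of them higher and 3 lower at +200 mV, holding 83 of its 418 protein-coding calls. Shuffled gene order put at most 18 calls into such runs. Shuffling breaks the shared movement of neighbours, which was also present between treatment libraries. The runs therefore cannot show a response to the potential. The longest runs had 6 genes and were higher. Pden_2067 belonged to a run of 4 lower genes, with log2 fold changes from -3.65 to -0.92. No gene in these runs passed edgeR's adjusted threshold, and the largest unadjusted edgeR p among them was 0.0332.

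**Figure D4:**
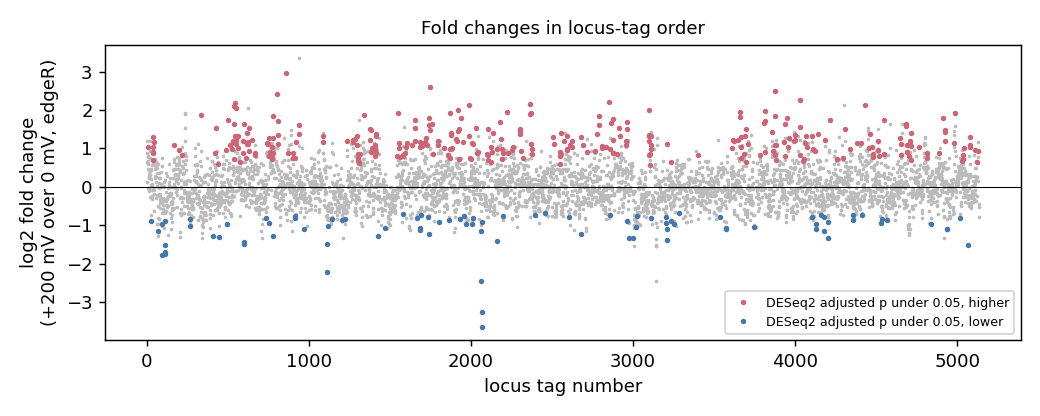
Log2 fold change of each protein-coding gene (vertical axis, +200 mV over 0 mV, edgeR) in order of locus-tag number (horizontal axis). Coloured points are genes with DESeq2 adjusted p under 0.05, with higher genes in red and lower genes in blue. The lowest blue point is Pden_2067 at -3.65.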

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

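The fits with library weights, a summed control and 1 copy of each mirrored gene pair, and all refits of DESeq2, were chosen after the data were seen. The other settings were fixed before the data were examined. In edgeR, DESeq2 size factors, no robust estimation and protein-coding genes only gave 0 higher and 0 lower genes, as did limma-voom, with unadjusted counts near the 595 and 439 of all libraries. Dropping the low-count filter changed no row and tests nothing. A fold threshold also tests nothing, since it can only remove calls and the main fit had 0. Leaving out each library gave 0 in both directions; with a lone control, that library is assumed to vary like the treatment libraries. The planned exceptions were the DESeq2 test (327 higher, 92 lower), library totals alone (1 lower, Pden_2067) and the replicate block (388 higher, 205 lower). Equal replicate numbers were not shown to pair the libraries, since deviations from the group means correlated across genes at 0.0296 for number 1 and -0.0631 for number 2. In the block fit treatment replicate 3 has no partner, so by construction only the other 4 libraries inform the difference. The block also leaves less replication than the main fit from which to estimate the spread. Without treatment replicate 3 and without a block, edgeR called 0 genes in both directions. The 4 named protein-coding genes passed with DESeq2, the block and library weights. tRNA-Pro2 passed with the same 3 settings and tRNA-Ala2 with library weights. The log2 fold change of the ribonuclease P RNA was 0.58 with the block and 0.56 with library weights. The block left the structural RNA list uncalled. Leaving out each library moved the number of called lists between 0 and 1, at camera's preset correlation. Library weights gave 684 higher and 522 lower genes, and a summed control or 1 copy of each mirrored pair gave 0 in edgeR. DESeq2 called 2 higher and 1 lower gene with a summed control, 465 and 198 with the block, and 126 and 19 at adjusted p under 0.01 with an absolute log2 fold change over 1. Leaving out each library gave 7 to 679 higher and 0 to 345 lower genes in DESeq2. Of its 419 calls, 297 were shared with the block fit, and 392, 201 and 403 with the fits lacking treatment replicate 1, 2 and 3. Signs reversed for 3 transcripts near 0. For the 2 less abundant rRNA rows, log2 fold changes ran from -0.20 to 0.029 and from -0.27 to 0.17 when each library was left out, and were 0.030 and 0.048 with library weights. The gene ffs ran from -0.85 to 0.27 when each library was left out and was 0.18 with the replicate block. The cause of these shifts was not tested. Depth limits the rows of low count, and at most 8 rows per library had under 10 counts.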

Other observations

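The tests of explanations and the mirrored pairs in this part were chosen after the results were seen, whereas the edgeR and DESeq2 tests on all libraries were planned. A block of genes had near-equal counts to another block in mirrored order. Protein-coding genes with locus numbers 1313 to 1328 matched genes 1584 down to 1569, making 16 consecutive pairs, and genes 1303 to 1311 matched 1593 down to 1585, another 9 pairs. A pair was called matching at an absolute log2 ratio under 0.5 in each of the 5 libraries. Over 10257 mirrored arrangements and 5128 same-order offsets tried, no other gave more than 4 consecutive pairs. The most counted pair held 1156249 and 1159744 counts, and the 25 pairs took 2.91% of all counts. Log2 fold changes differed by at most 0.18 between copies. DESeq2 called 8 of the copies. If the copies share reads, which was not tested on sequence, their separate values are uncertain.

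Reads that fit both copies are a possible explanation for the mirrored pairs. Copies identical throughout, with every read counted in both, would have equal counts, whereas the median chi-square of copy against copy was 1.06, above the 0.455 of sampling noise. Reads split between near-identical copies and separate transcription at similar levels cannot be told apart, because no sequence was used here. The mean chi-square was 2.39, somewhat above sampling noise, while genes of nearest total count gave a median of 34.3.

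DESeq2 called 419 genes where edgeR called 0, with 1034 at an unadjusted p under 0.05. For the 4 named protein-coding genes both tools gave similar log2 fold changes. Pden_2225 had 1.94 ± 0.23 (SE) in edgeR and 1.97 ± 0.24 in DESeq2, and Pden_1760 had 1.64 ± 0.20 and 1.67 ± 0.20. Pden_2067 had -3.65 ± 0.40 and -3.62 ± 0.44, and Pden_5069 had -1.53 ± 0.20 and -1.50 ± 0.24. For these 4, chosen by small p, the gap therefore lay in how each test turns such values into a p. Whether this holds for the other calls was not tested. The values argue against ribosomal RNA load as the sole source of the pattern. The controls differed by 6.58 percentage points in rRNA share at an SD of log2 ratios of 0.184, while the 4 pairs that differed less had SDs of 0.543 to 0.907. A candidate explanation for the DESeq2 calls is that both control libraries came from 1 culture. The labels do not state this, and the design text speaks of replicate cultures. The SD of 0.184 between the controls lay below the 0.529 of the closest treatment pair. Simulations of 1 control culture with no gene changed gave 97 to 153 genes at DESeq2 adjusted p under 0.01 with an absolute log2 fold change over 1 and 0 to 40 edgeR calls, ranges that hold the real 145 and 0, but 261 to 338 DESeq2 calls, 59.6% to 74.4% of them higher, and 873 to 972 genes at an unadjusted edgeR p under 0.05, short of the real 419, 78.0% and 1034. A wider spread at +200 mV with 2 control cultures gave at most 2 calls in simulations, but simulated genes were independent whereas real neighbours correlated at 0.440 to 0.473, so neither set of simulations decides. Genes with all treatment libraries on the same side of both controls made up 48.3%. Chance gives 50% if 1 control culture gave 2 equal libraries, and 20% for 5 independent libraries of equal spread. The controls differed from each other and spread less than the treatment libraries, so neither value is exact here. This share therefore cannot tell a response to the potential from the deviation of a single control culture.

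The 10 splits of the 5 libraries are too few for a share under 0.05. As many calls came from 2 of them, the real split with 419 and treatment replicates 1 and 2 against the rest with 698.

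The mean share of ribosomal RNA was 22.0% at +200 mV and 15.5% at 0 mV, a difference that did not pass (exact permutation p = 0.3), and a control at 18.7% lay above a treatment library at 18.1%. Uneven removal of ribosomal RNA may account for the difference, but removal was not measured. The share differed 1.54-fold between the 2 controls, whose protein-coding genes were close, and 1.42-fold between the group means. Single libraries vary more than group means, so these ratios are not like for like. A biological change in ribosomal RNA was not tested.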
